A study of Homo sapiens with 8 samples.

How the data were processed

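The deposited data were total RNA sequencing of K562 cells, an established human erythroleukaemia line; a label describes the cells as epithelial. The cells carried SF3B1, the largest subunit of the SF3b complex of the U2 snRNP, either as wild type or with the K700E hotspot substitution, and the modified allele was induced with doxycycline. RNA was sampled at day 4 and day 8, with 2 libraries per group and 8 in all. Libraries were strand-specific and paired-end, per the labels' protocols. Nothing in the labels says that replicates came from separate cultures, so the spread between these libraries may be technical. The p-values of tests between libraries measure only that spread. Fisher's exact and permutation tests instead took acceptors or genes of the same libraries as independent units, so their p-values do not measure it.

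Reads were trimmed with cutadapt and aligned with STAR to hg38, per the submitters' processing notes, and the aligner was STAR 2.7.0e, per the file headers. The index held GENCODE release 29 junctions and GENCODE release 22 was added at mapping, per the file headers. Alignment was end to end in 1 pass, and settings were the same in every library. Per the file headers, an unannotated junction with a canonical motif needed an overhang of at least 12 nt and 1 uniquely mapped read, and one with another motif an overhang of 30 nt and 3 such reads. A read could map to up to 10 places. The deposited values are the counts of uniquely mapped and of multi-mapped reads across each splice junction, not normalized. The files also give a motif code, an annotation flag and the maximum overhang, which were used as descriptions.

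The union of the 8 libraries held 860791 junctions with a defined strand on the autosomes and X. Junctions were matched to GENCODE release 29, the release of the index; 99.9% of those flagged as annotated were in it. Positions are 1-based, on hg38, and an acceptor is given as the last base of its intron. Percent usage of a junction was its unique reads over all unique reads of the shared donor, given where that total was 10 or more. For donor usage the total was that of the shared acceptor. Junctions with 5 unique reads in at least 2 libraries were tested where the shared site had at least 2 such junctions and a mean of 20 reads per library. Tests used edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood fit, diffSpliceDGE), with junctions grouped by donor for acceptor usage and by acceptor for donor usage. A junction was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 5 percentage points. The reference acceptor of a donor was the most used one in the wild-type libraries, and a near-upstream acceptor lay 5 to 50 nt upstream of it.

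Gene-level counts were unique reads over annotated introns of 1 gene, so only spliced genes were measured; introns that belong to 2 genes carried 4.17% of unique reads and were left out. Genes passing edgeR's expression filter were tested with the quasi-likelihood test at an adjusted p under 0.05. Normalised values are CPM from edgeR with TMM factors. The 22 gene lists, chosen before the data were examined, were tested with limma 3.58.1 (camera, preset correlation 0.01) and again with an estimated correlation. Genes with reads from near-identical copies, such as the metallothioneins MT1X and MT2A or SIGLEC14, are uncertain to that extent.

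The design set before the data were examined fitted all 8 libraries in 1 model with 4 groups and took contrasts for the mean of both days, each day, their interaction and the day effects. It also named, as an alternative, a fit of the 4 libraries of each day alone. The day 4 fit is given first in the results, a choice made after the day 8 libraries were seen to disagree with their labels; no library was moved to another group. Named genes follow a rule set before the data were examined: SF3B1; the 10 near-upstream acceptors with the largest gain and no overlap between genotypes; the tested near-upstream acceptors of a list of 30 known SF3B1 hotspot targets; the 3 largest gains and losses of other acceptors and of donors; the 8 largest rises and falls at gene level with a mean of at least 50 reads and no overlap; up to 4 members per list; and 5 genes each way for day effects. Some items that the rule names are not reported here. The rule asked for no overlap at both days and was applied to the day 4 libraries alone, a change made after the values were seen. In the test of frame, gene counts left out the affected donors; other gene-level values include them. The permutation tests used 100000 resamples. The planned comparison of base composition upstream of cryptic acceptors needs a genome sequence and was not run.

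The steps were tested on simulated data drawn from the real means and depths and from the trend of dispersion with mean. The spread particular to each junction or gene was left out, so false calls in the real data may be more frequent. Changed acceptors were little-used ones whose reference acceptor was well covered, a narrower set than that tested. In the day 4 simulation, run on 68765 junctions, 38 of 100 acceptors that took 10% of the reference acceptor's reads were called and 72 of 100 that took 30%, with 0 false calls among 110. In the day 4 gene-level simulation, run on 13687 genes, 48 of 100 genes changed 2-fold and 77 of 100 changed 4-fold were called, with 4 false calls among 129. With all 8 libraries, 41 and 80 of 100 acceptors were called among 87268 junctions, with 3 false calls among 124. Of the genes, 40 and 69 of 100 were called among 14502, with 9 false calls among 118 (7.63%), above the set rate of 0.05.

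Alternatives were RLE size factors, no count filter, the replicate number as a block, leaving out each library, limma diffSplice, DESeq2 1.42.0, other minimum changes, multi-mapped reads, equal depth, a longer overhang, annotated junctions only and all junctions sharing an annotated site of the gene. Unique junction reads ranged from 49338071 to 77750812 per library. Intervals on single libraries are 95% Wilson intervals, which cover counting error only. They take reads as independent, and PCR copies are not independent molecules, so the intervals may be too narrow.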

Results

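Splice junctions were counted in total RNA of K562 cells, a human erythroleukaemia line, that carried SF3B1 as wild type or with the K700E substitution. SF3B1 is the U2 snRNP subunit that helps recognise the branch point upstream of a 3' splice site (acceptor), and K700E is a substitution recurrent in myelodysplastic syndromes. Each genotype had 2 libraries at day 4 and 2 at day 8 of doxycycline induction. The wild-type libraries held 60922615 and 73538969 unique junction reads at day 4 and 71039050 and 61234203 at day 8. The K700E libraries held 77750812 and 65890014 at day 4, and those labelled K700E at day 8 held 49338071 and 60953200. The number of junctions listed per library ranged from 211347 to 470900, with the lowest values, 211347 and 278644, in the libraries labelled wild type at day 8.

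The SF3B1 gene (ENSG00000115524.15, chromosome 2, 197389784 to 197435091 on hg38, minus strand) had 39938 and 40557 junction reads in the wild-type and 52174 and 42582 in the K700E libraries at day 4. Its normalised level was 707 CPM ± 71.0 (SD, n = 2) in wild type and 719 CPM ± 12.6 in K700E, a log2 change of 0.03 (SE 0.12, adjusted p 0.922 by edgeR). Junction counts do not read the K700E base, so the genotype labels were compared with the acceptors known to respond to it. At day 8 SF3B1 had 31353 and 25651 reads in the libraries labelled wild type and 22705 and 25826 in those labelled K700E.

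Known target acceptors followed the labels at day 4 and not at day 8. The median use of the cryptic acceptors of known SF3B1 hotspot targets was 1.22% and 1.84% in the wild-type and 23.7% and 25.4% in the K700E libraries at day 4. At day 8 it was 0% and 33.0% in the libraries labelled wild type and 1.88% and 24.5% in those labelled K700E. In TMEM14C, a mitochondrial inner membrane protein needed for porphyrin import, the cryptic acceptor took 70.7% of donor reads (Wilson 95% interval 68.3% to 73.1%) in the library labelled wild type day 8 replicate 2. It took 11.2% (9.55% to 13.0%) in the library labelled K700E day 8 replicate 1, 4.17% (3.37% to 5.16%) in wild type day 8 replicate 1 and 70.3% (67.9% to 72.5%) in K700E day 8 replicate 2. In MAP3K7, the kinase TAK1 of NF-kB signalling, these libraries gave 77.2% (71.7% to 81.9%) and 14.7% (11.2% to 19.1%) for the first pair. In DLST, a subunit of the 2-oxoglutarate dehydrogenase complex, the library labelled wild type day 8 replicate 1 had 0 of 302 reads, with an upper bound of 1.26%. Rare junctions were few in wild type day 8 replicate 1. At equal depth 4.66% of its unannotated junctions had 1 read, against 37.6% to 45.9% in the libraries not labelled wild type at day 8. A loss or filter of rare junctions would lower small values of use. The median of 0% and the upper bound in that library may thus be too low. No library was moved to another group, and day 8 values are given under their labels.

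**Figure D1:**
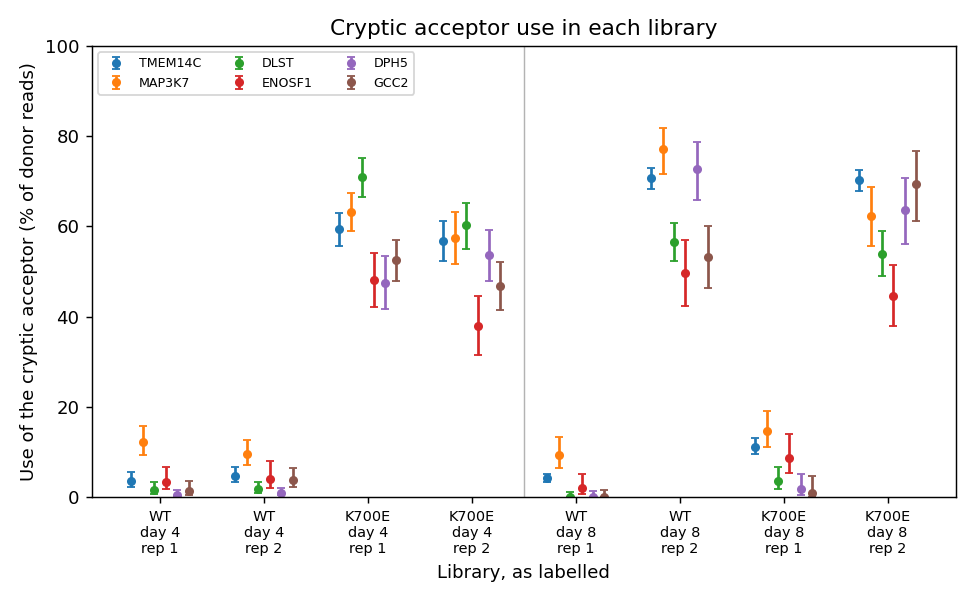
Use of the cryptic acceptor (percent of the donor's unique reads, y axis) of 6 known target genes in each of the 8 libraries as labelled (x axis), with Wilson 95% intervals. At day 8, 1 library of each label lies nearer to the other genotype's day 4 libraries than to its own, as for TMEM14C, with 70.7% in wild type day 8 replicate 2 and 11.2% in K700E day 8 replicate 1.

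The first comparison asked which acceptors changed between genotypes over both days. With all 8 libraries in 1 model, edgeR called 0 of 95636 acceptors for the mean of both days, and 5123 (5.36%) had an unadjusted p under 0.05. It called 0 for day 4 (2292 unadjusted), 0 for day 8 (6887) and 0 for the interaction (5654), and limma diffSplice also called 0 for each. Donor usage gave 0 calls of 87639 (4359 unadjusted), and limma diffSplice gave 0. Without the library labelled wild type day 8 replicate 2 edgeR called 469 acceptors for the mean of both days, 27 for day 4, 634 for day 8, 3 for the interaction and 147 donor junctions. Without wild type day 8 replicate 1 it called 36 for day 4 and 38 for the interaction. A fit of the day 8 libraries alone called 0 of 63775 acceptors (1779 unadjusted).

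The second comparison asked which acceptors differed at day 4 alone, where the target acceptors followed the labels. Among 70418 acceptors tested in the 4 day 4 libraries, 323 at 307 donors in 283 genes were called, 248 with higher and 75 with lower use in K700E. The excess of higher calls was smaller with limma diffSplice, with 150 higher and 137 lower, and without K700E replicate 1, with 56 higher and 53 lower. Near-upstream acceptors made up 149 of the 248 higher calls (60.1%), 2 of the 75 lower calls (2.67%, Fisher's exact p 1.35e-21) and 1945 of 40453 non-reference acceptors not called (4.81%, odds ratio 29.8, 95% interval 22.9 to 39.0, exact p 6.8e-126). Of those 1945, 79 had an adjusted p under 0.05 and a change under 5 points, and without such acceptors the share was 1866 of 40258 (4.64%). Both lower ones, named after their values were seen, were in PLAGL1, an imprinted zinc finger gene, and in the gene ENSG00000267002. The contrast with lower calls was partly fixed in advance. Of the 75, 15 were reference acceptors, which cannot be near-upstream, and an acceptor used under 5% in wild type cannot fall by 5 points. Of 2096 near-upstream acceptors tested, 7.11% were called higher, against 0.518% of 3668 1 to 50 nt downstream. The higher ones lay in 142 genes, 32 were annotated, and the gain had a median of 14.5 points, from 5.11 to 70.9, with 58 above 20 points. They lay a mean of 18.2 nt ± 5.06 (SD, n = 149) upstream of the reference acceptor against 23.5 ± 9.78 (n = 1866) for those with an adjusted p over 0.05, a difference of -5.36 nt (two-sided permutation p 1e-05, the smallest the resamples can give). Against all 1945 not called the difference was -5.19 nt, with the same permutation p. The exact and permutation tests took acceptors as units, not libraries. Of those called, 143 lay 10 to 30 nt upstream (96.0%, against 75.5% of those with an adjusted p over 0.05). The calls rest on 2 libraries per group and fell to between 8 and 109 when 1 of the 4 libraries was left out, with 8 without wild-type replicate 2, 23 without wild-type replicate 1, 109 without K700E replicate 1 and 71 without K700E replicate 2.

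**Figure D2:**
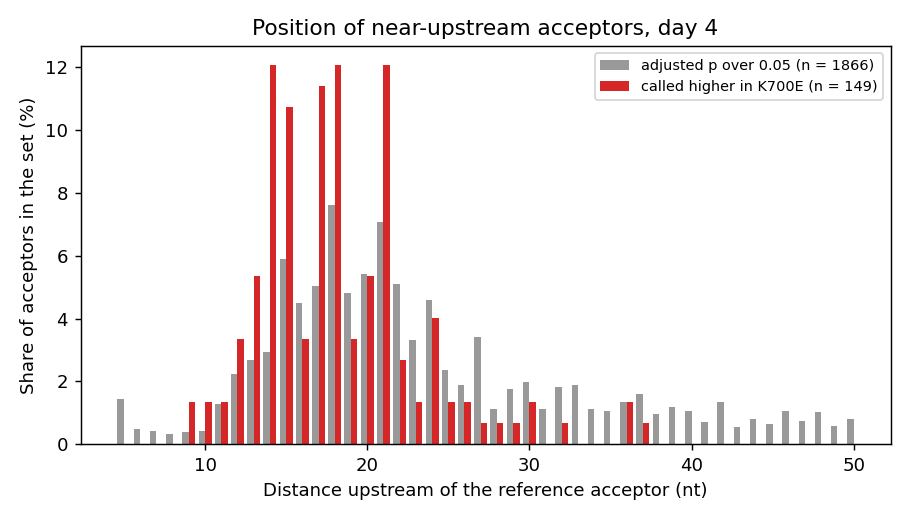
Share of near-upstream acceptors (percent of the set, y axis) by distance upstream of the reference acceptor in nt (x axis), for 149 called higher in K700E at day 4 and 1866 with an adjusted p over 0.05. The called ones have a median distance of 17 nt against 21 nt.

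The near-upstream acceptors with the largest gains were in 9 genes. MFSD9, a putative transporter, used an acceptor on chromosome 2 at 102732427, 17 nt upstream of 102732410, in 1.04% ± 1.47 (SD, n = 2) of donor reads in wild type and 71.9% ± 14.0 in K700E (adjusted p 0.0139). In DLST, on chromosome 14, the acceptor at 74889877, 19 nt upstream of 74889896, rose from 1.75% ± 0.128 to 65.6% ± 7.65 (adjusted p 3.92e-06). SEPSECS, which makes selenocysteinyl-tRNA, used an unannotated acceptor 23 nt upstream that had 0% in wild type and 60.5% ± 19.8 in K700E at day 4. At day 8 this acceptor had 43.1% and 55.6% in the libraries labelled wild type and 0% and 60.0% in those labelled K700E. Its use in wild type day 8 replicate 1 was thus unlike that at day 4. ADGRV1, an adhesion receptor, gained acceptors at separate introns, to 62.4% ± 0.257 at 21 nt and to 57.1% ± 7.02 at 10 nt. In TMEM14C, on chromosome 6, the acceptor at 10724555 lay in the 5' UTR and added CTTGTTTTCTGCAG, and its use rose from 4.20% ± 0.815 to 58.1% ± 1.82 (adjusted p 5.36e-06). MYL4, an atrial and embryonic myosin light chain, rose to 56.8% ± 4.30 at an acceptor 13 nt upstream in its 3' UTR. The noncoding VPS9D1-AS1 rose to 55.2% ± 15.0 at 15 nt, and CCDC66, a centrosomal protein, to 56.5% ± 2.61 at 18 nt. DPH5, a methyltransferase of diphthamide synthesis, rose from 0.715% ± 0.377 to 50.6% ± 4.4 at 14 nt (adjusted p 4.6e-06).

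Of 30 known hotspot targets, 20 had a near-upstream acceptor tested at day 4, 13 of these were called higher and 0 lower by edgeR, and 14 were higher when adjusted over the list alone. MAP3K7 rose from 10.9% ± 1.93 to 60.4% ± 4.09 at 20 nt (adjusted p 0.00196), GCC2, a golgin, from 2.63% to 49.6%, and ENOSF1, a mitochondrial enolase-like enzyme, from 3.73% to 43.0%. SEPTIN6, a cytoskeletal GTPase, rose from 2.78% to 40.1%, TTI1, a scaffold of PI3K-like kinases, from 1.66% to 34.9%, and ZDHHC16, a palmitoyltransferase, from 1.90% to 31.7%. PPP2R5A, a regulatory subunit of PP2A that acts on MYC, rose from 1.80% to 21.3%, and OXA1L, the inner membrane insertase, from 1.99% to 16.5%. METTL5, an 18S rRNA methyltransferase, rose from 1.45% to 11.8% and ERGIC3, a cargo receptor, from 0.782% to 9.57%. Several were not called. BRD9, a noncanonical BAF subunit, rose by 3.47 points (adjusted p 0.115). ORAI2, a calcium channel subunit, rose by 50.1 points with K700E libraries at 91.7% and 32% (adjusted p 0.495). PPOX, of haem synthesis, rose by 22.4 points (adjusted p 0.867), STAU1, an RNA-binding protein, by 5.62 points (adjusted p 1.00), ANKHD1 by 1.58 points (adjusted p 0.0570) and SERBP1 by 0.460 points (adjusted p 0.440).

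Other acceptors changed as well. COASY, the last enzyme of coenzyme A synthesis, used an acceptor 256 nt upstream of the reference in 5.82% ± 3.18 of reads in wild type and 89.4% ± 0.666 in K700E. MTERF2, a mitochondrial transcription factor, rose from 19.9% to 88.0% at an acceptor 10 nt downstream, and the noncoding CRNDE from 15.5% to 82.5% at one 83 nt downstream. The largest losses were at the reference acceptors of GEN1, a Holliday junction resolvase, from 73.6% ± 15.7 to 6.88% ± 2.46, of LINC01138 from 67.9% to 10.7%, and of PGBD1, a transposase-derived gene, from 60.7% to 6.87%. On the donor side 16 of 65156 junctions were called, 7 higher and 9 lower, with 0 without either wild-type library, 58 without K700E replicate 1 and 9 without K700E replicate 2. Of the called ones, 0 higher and 0 lower lay within 50 nt of the acceptor's most used wild-type donor, and the nearest lay 190 nt away. Exon inclusion or skipping may underlie the called changes, but was not told apart from use of a more distant alternative donor. As a share of the acceptor's reads, ECT2, which acts in cytokinesis, rose from 7.58% to 47.8%, TMEM214, of ER stress, from 18.1% to 53.8%, and HNRNPA2B1, a splicing regulator, from 12.3% to 37.3%. CBX5, the heterochromatin protein HP1 alpha, fell from 44.0% to 8.79%, ADCK1 from 28.7% to 0.391% and HSPH1, a chaperone of the HSP110 family, from 29.5% to 8.44%.

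The third comparison asked which spliced genes changed in level. In the 8-library model edgeR called 0 of 14902 genes for the mean of both days (1383 unadjusted; DESeq2 107), 0 for day 4 (1449; DESeq2 270), 0 for day 8 (1132; DESeq2 65) and 0 for the interaction (1371; DESeq2 193). The day 8 libraries alone gave 0 of 13990 (408 unadjusted). The spread of gene counts between libraries of a group, as the biological coefficient of variation, was 0.432 over the 8 libraries, 0.277 at day 4 alone and 0.516 at day 8 alone. The day 4 libraries alone gave 74 of 13991 genes, 32 higher and 42 lower in K700E, with 2979 at an unadjusted p under 0.05 and 1640 called by DESeq2. The count was 0 without either wild-type library, 2536 without K700E replicate 1 and 1255 without K700E replicate 2. The calls were thus lost without either wild-type library and rose without either K700E library.

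ADCY2, an adenylate cyclase, had 0 reads in both wild-type libraries and 16.0 CPM ± 0.837 (SD, n = 2) in K700E, at least 303-fold higher against a floor of 3 reads per library. SEMA6A, a semaphorin, was at least 65.5-fold higher on that floor. VPS35L, a subunit of the Commander endosomal complex, rose from 5.20 CPM ± 1.63 to 113 CPM ± 1.06, a log2 change of 4.44 (SE 0.26, adjusted p 0.0190). At day 8 VPS35L had 6.70 and 117 CPM in the libraries labelled wild type and 2.53 and 138 in those labelled K700E. The log2 change was 5.57 in AADAT, of lysine breakdown, and 5.13 in SIGLEC14, whose near-identical copy SIGLEC5 shares reads. It was 4.66 in TEK, the angiopoietin receptor, and 4.50 in GRAMD2B. Among falls, ZFAND4 was at least 70.6-fold lower and CEP41, a ciliary tubulin-modifying factor, at least 55.4-fold lower, on the same floor. The log2 change was -6.25 in WDR72, -6.13 in ASXL3, a Polycomb-associated protein, -5.81 in RNF180 and -4.95 in GLIPR1. MT1X, a metallothionein, fell from 42.8 CPM ± 14.5 to 1.59 CPM ± 0.0143, a log2 change of -4.74, and TBX15, a T-box factor, had -4.64.

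Of the 22 gene lists at day 4, camera with the preset correlation placed 7 at an adjusted p under 0.05, and with an estimated correlation 0 did, the lowest adjusted p being 0.706. R-loop processing genes were higher in 15 of 15 members (median log2 change 0.33, adjusted p 0.000766, 0 called by edgeR, 1 adjusted over the list alone), with THOC1 at 0.63 and RNASEH2C at 0.68. Unfolded protein and integrated stress response genes were lower (median -0.67, adjusted p 0.00112, 0 of 11 called by edgeR, 1 lower adjusted over the list alone), with ATF3 at -1.77, DDIT3 at -1.43 and DNAJB9 at -1.10. ATF3 had 46.2 and 80.7 CPM in the wild-type day 4 libraries and 4.50 to 22.1 in the other 6. CPOX, of haem biosynthesis, was called lower (-1.29, SE 0.13, adjusted p 0.0344), and SLC25A38, the glycine importer, had -1.46. Megakaryocyte markers were higher (median 2.88, adjusted p 0.00210), and ITGA2B rose from 16.5 CPM ± 6.52 to 99.7 CPM ± 0.552 (log2 change 2.60, adjusted p 0.0418), with 4 of 7 higher adjusted over the list alone, among them THBS1 (4.13) and ITGB3 (2.40). At day 8 ITGA2B had 6781 and 4260 reads in the libraries labelled wild type and 1591 and 29708 in those labelled K700E. Epithelial markers were lower (median -0.53, adjusted p 0.00210, 0 of 7 called by edgeR, 4 lower adjusted over the list alone), with ELF3 at -5.36 and KRT18 at -0.84. ELF3 had 16.1 and 6.04 CPM in the wild-type day 4 libraries and 0.017 to 1.42 in the other 6. Genes of the U2 snRNP and 3' splice site recognition were higher (median 0.13, adjusted p 0.0180, 0 of 23 called by edgeR, 2 higher adjusted over the list alone), with SUGP1 at 0.93 and DDX46 at 0.74. Serine synthesis genes were lower (median -0.25, adjusted p 0.0386, 0 of 8 called by edgeR, 2 lower adjusted over the list alone), with PHGDH at -1.52 and SHMT2 at -0.66. PHGDH had 372 and 438 CPM in the wild-type day 4 libraries and 118 to 263 in the other 6.

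The other lists did not pass at day 4. The hotspot targets as genes had a median log2 change of -0.11 (adjusted p 0.0632), with PPP2R5A at -1.05 and DPH5 at -1.08. The adjusted p was 0.0662 for erythroid markers, 0.0932 for interferon response, 0.176 for DNA replication, 0.270 for both mitosis and replication stress, and 0.292 for nonsense-mediated decay factors. It was 0.293 for MYC and nucleolar targets, which had LDHA called at -1.55, 0.354 for heat shock, 0.370 for RNA polymerase II elongation, where RTF1 had -1.04, and 0.393 for myeloid markers. It was 0.597 for each of SIN3 and HDAC, respiratory complex III and NF-kB targets. It was 0.944 for lymphoid markers, whose median was -0.28 and mean 0.47. For the mean of both days in the 8-library model 9 lists passed with the preset correlation and 0 with the estimated one, with DNA replication highest in rank (median 0.22, adjusted p 0.000256).

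The fourth comparison asked whether gained acceptors whose distance is not a multiple of 3 go with lower gene levels, since such a shift can expose a coding transcript to decay. With the affected donors left out of the counts, 73 genes with a frame-shifting distance had a median log2 change of -0.29 and 67 with a distance that is a multiple of 3 had -0.01 (difference -0.29, two-sided permutation p 9e-05). Lower levels were found in 58 of the 73 and in 34 of the 67. Untranslated and noncoding genes were included, and the test used genes chosen by their acceptors in these libraries. It took genes as units, not libraries. ADGRV1, with gained acceptors of both kinds, was counted once, by the gain of 59.3 points at 21 nt, a multiple of 3.

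**Figure D3:**
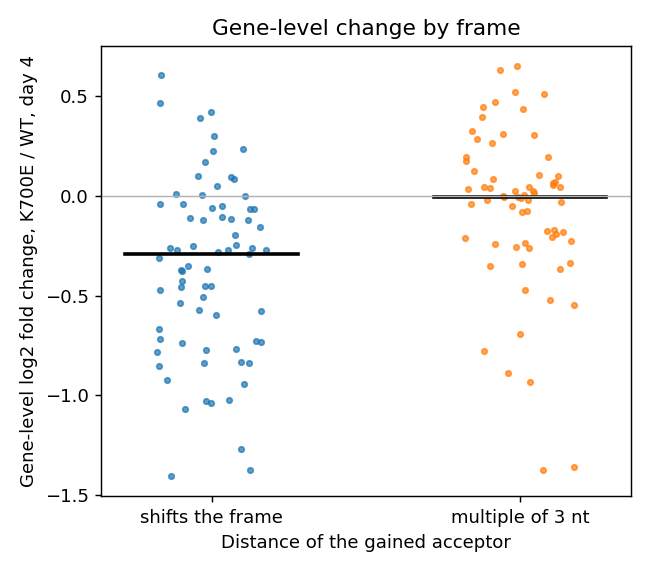
Gene-level log2 change of K700E over wild type at day 4 (y axis), each point 1 gene with a gained near-upstream acceptor, by whether the distance shifts the frame (x axis); bars are medians. The medians are -0.29 over 73 genes and -0.01 over 67 genes.

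The last comparison asked what differed between day 8 and day 4 within each label. Among libraries labelled wild type 3029 genes were called, 1427 higher and 1602 lower at day 8, and among those labelled K700E 2823, 1525 higher and 1298 lower. With the wild-type label, NCLN, a nicalin of ER membrane complexes, rose by 1.82 on the log2 scale, PIK3C2B by 2.29, EMC10 by 2.38, SLAMF6 by 3.55 and TTYH3 by 2.40, and the mitotic genes KIF20A (-2.64), CCNA2 (-2.20), BUB1 (-1.98), PRR11 (-1.93) and PTTG1 (-2.08) fell, each with an adjusted p of 0.00453. With the K700E label, SLC52A2, a riboflavin transporter, rose by 2.7, EMC10 by 2.52, NCLN by 1.81, PEPD by 2.48 and TTYH3 by 2.47, and PRR11 (-1.96), CENPE (-2.30), BUB1 (-1.77), TUBE1 (-2.23) and IQCB1 (-2.18) fell, each with an adjusted p of 0.00726. The run directories of all day 4 libraries carry 1 month and those of the day 8 libraries others, so day and run cannot be told apart. Those of the libraries labelled wild type and K700E at day 8 also carry different months, so run and genotype label cannot be told apart at day 8 or in the interaction. The count for the wild-type label was 135 without day 4 wild-type replicate 1 and 0 without replicate 2. That for the K700E label was 432 and 0 without the day 4 K700E replicates 1 and 2, 1499 and 1532 without the day 4 wild-type replicates, and 1808 and 709 without the day 8 K700E replicates.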

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

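Fitting the libraries of 1 day alone was planned, but the settings tried on the day 4 fit, and the crossed pairing (2624 genes for the day effect in K700E), were chosen after the results were seen; the others were planned.

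With all 8 libraries, size factors, multi-mapped reads, equal depth, overhang, the minimum change and the replicate block left the 0 calls at 0. Without the count filter the mean of both days had 19 acceptors, 16 of them near-upstream, 2 donor junctions and 41 genes; day 4 had 65 acceptors and 126 genes; day 8 had 1 acceptor; and the interaction had 31 acceptors and 102 genes. DESeq2 called 107 genes for the mean, 270 for day 4, 65 for day 8 and 193 for the interaction. The cause was not tested. Fitting only the libraries of that day gave 323 acceptors and 74 genes at day 4. Leaving out 1 library in turn gave 0 to 469 acceptors and 0 to 121 near-upstream ones for the mean, 0 to 36 at day 4, 0 to 634 at day 8, 0 to 38 for the interaction and 0 to 147 donor junctions. The highest values came without the library labelled wild type day 8 replicate 2, except 36 and 38, which came without replicate 1. A lone library left in a group was assumed to vary like the other groups.

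In the day 4 libraries alone, size factors, multi-mapped reads, equal depth and a longer overhang kept each count within 1.5 times. The acceptor count was 213 with at least 10 points, 518 with no minimum change (227 near-upstream) and 86 with annotated junctions only (30 near-upstream), as fewer or more junctions can then be called. limma called 287 acceptors, 150 higher and 137 lower, with 64 near-upstream, and 79 donor junctions. Donor junctions numbered 32 with no minimum change, 36 with no filter and 8 with the replicate block. Genes numbered 1567 with no filter, 126 with the replicate block and 1640 by DESeq2, and the cause was not tested. Leaving out 1 library gave 8 to 109 acceptors, 4 to 40 near-upstream acceptors, 0 to 58 donor junctions and 0 to 2536 genes. The frame difference was -0.29 with the affected donors included.

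The replicate numbers gave no pairing that held across groups: deviations of replicate 1 from the group mean correlated across genes at 0.0964 between the day 4 groups, 0.246 between the day 8 groups, 0.0765 between the wild-type days and -0.177 between the K700E days. They correlated at 0.170 between K700E day 4 and wild type day 8 and at 0.0203 between K700E day 8 and wild type day 4. At day 8 the replicate number went with the median use of known target acceptors. That use was 0% and 1.88% in the libraries labelled wild type and K700E replicate 1, and 33.0% and 24.5% in those of replicate 2. The correlation between the day 8 groups and the replicate block may carry this difference, which was not tested. For the day effects, leaving out 1 library gave 0 to 2960 genes for the wild-type label and 0 to 3776 for the K700E label. The latter was 1871 with a log2 change of at least 1 and 4347 by DESeq2. The gene lists passing fell to 0, at day 4 and for the mean of both days, with an estimated correlation. The planned sequence comparison over 25 and 40 nt was not run, since no genome sequence was at hand, and the frame test for the mean of both days has no value with 0 calls. At equal depth the day 4 acceptor count was 307.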

Other observations

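The tests of glycolytic enzymes, of day 8 acceptor use against the labels, of the 1-read junctions, of the deficit removed by equal depth and of run directories were chosen after the results were seen; those of long genes, the ratio at equal depth, the most counted genes and the splits of the libraries were written before.

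Glycolytic enzymes were lower in K700E at day 4, a pattern noticed among the called genes. Of 17 measured enzymes 5 were called and fell: ALDOA (log2 change -1.96, adjusted p 0.0190), LDHA (-1.55), GPI (-1.25), GAPDH (-0.83) and PGK1 (-0.96). Of the 12 not called 11 were lower, with a median log2 change of -0.65 (-0.649), from -2.55 in ALDOC to 0.34 in PFKP. LDHA had 2573 and 2922 CPM in the wild-type and 903 and 965 in the K700E libraries. At day 8 it had 985 and 652 CPM in the libraries labelled wild type and 779 and 677 in those labelled K700E. For LDHA the wild-type day 4 libraries thus stood apart from the other 6, and ALDOA, GPI, GAPDH and PGK1 were also highest there. PKM, TPI1 and PGAM1 were not, and in these the K700E day 4 libraries were lowest. PKM had 1061 and 956 CPM in wild type and 464 and 307 in K700E at day 4, and 872 to 1778 at day 8. PHGDH, SLC25A38, CPOX and the stress genes ATF3, DDIT3 and DNAJB9 stood apart in the same way as LDHA. PHGDH had 372 and 438 CPM in the wild-type day 4 libraries and 118 to 263 in the others, SLC25A38 45.3 and 57.0 against 17.3 to 38.3, and CPOX 116 in both against 17.4 to 50.6. ATF3 had 46.2 and 80.7 CPM against 4.50 to 22.1, DDIT3 62.7 and 118 against 7.74 to 43.4, and DNAJB9 17.3 and 20.3 against 4.16 to 11.99. PDK1, P4HA1 and the metallothioneins MT1X and MT2A, which like LDHA and ALDOA can respond to hypoxia or metal, were also called lower at day 4. The culture state of the wild-type day 4 cells, such as density or oxygen, may account for the genes in which those libraries stood apart, and was not tested.

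At day 8, 1 library of each label lay nearer in acceptor use to the other genotype. On an index set to 0 at the wild-type and 1 at the K700E day 4 mean, over 149 acceptors called at day 4, the library labelled wild type replicate 2 had a median of 1.11 and the library labelled K700E replicate 1 had 0.0116. Over 71 genes called at day 4 they had 1.04 and 0.248, though wild type replicate 1 also had 0.358. RNA mixed in like parts would leave both midway between the genotypes, and the larger distance from 1 or 0 was 0.112. That leaves a small share of other RNA open, as TMEM14C had 11.2% in K700E replicate 1 against 3.63% and 4.78% in wild type at day 4. Low complexity of the libraries labelled wild type was predicted to shift most the one with fewest junctions, whose index was -0.00678. This value cannot decide, since a loss of rare junctions would itself bring the index toward 0. The library labelled K700E replicate 1, also out of place, had 147784 unannotated junctions at equal depth, against 42601 and 82166 in those labelled wild type. An effect that changed with time would move both libraries of a label alike, while they differed by up to 1.12. An exchange of labels between 1 wild-type and 1 K700E library may explain the values, and separate wrong labels, or a loss of the modified allele in 1 culture with a gain in another, remain open, since no read of the K700E base was used here.

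The libraries labelled wild type at day 8 had few unannotated junctions. At equal depth they had 42601 and 82166, against 142279 to 182924 in the other 6, and the higher of them was 0.543 of the others' median. Equal depth removed 8.93% of its deficit, and wild type day 8 replicate 1, with 71039050 unique reads, had the fewest junctions, which argues against lower depth as the cause. The 20 most counted genes took 1.08 times the median share of the other libraries, which argues against a few genes taking the reads. The share of unannotated junctions with 1 read was 4.66% and 8.47%, 0.198 of the others' median at most, which is consistent with fewer distinct molecules read repeatedly or with a filter on rare junctions. These libraries share a run directory month that no other library has, so run and group cannot be told apart, and no biological explanation was tested.

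The gene-level differences between day 8 and day 4 may come from culture time or from sequencing batch. Over the run directory names, 0 months held libraries of both days, so the run directory and the day cannot be told apart.

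The planned genotype comparisons over all 8 libraries gave 0 calls, so all 35 splits into 4 and 4, the real one included, gave as many by construction and their number says nothing about chance. The highest other counts were 307 acceptors, 185 near-upstream acceptors, 123 donor junctions and 5050 genes. The split with the 4 day 4 libraries on 1 side gave 20 acceptors, 123 donor junctions and 5050 genes, which points to a structure by day. The split with both wild-type day 4 libraries, wild type day 8 replicate 1 and K700E day 8 replicate 1 on 1 side gave 307 acceptors, 185 of them near-upstream, and 359 genes, which points to the structure described above.

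Long genes were tested because slower transcription elongation could lower their counts in K700E. The median log2 change of 2744 genes over 100 kb minus that of 4864 genes under 20 kb was 0.06 (0.056), against 0.06 and 0.01 in the other splits of the 4 day 4 libraries. In 1210 long genes the log2 ratio of reads in the last to the first part of the gene changed by 0.03 (0.031), against 0.03 and 0.02 in the other splits. Neither value stood out from the other splits, and neither was negative, so both argue against the lower counts of long genes and the fall toward the 3' end in K700E that were looked for, and say nothing about small changes. The reads counted cross introns already spliced out, so they do not measure elongation itself, and no conclusion on elongation is drawn.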
